A study of Mus musculus with 8 samples.

How the data were processed

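Decidua was taken from wild-type mouse dams at E13.5 of pregnancy, 24 hours after an injection of saline or polyIC, with 4 libraries in each group. Per the labels' protocols, total RNA was extracted with TRIzol, polyadenylated RNA was selected on poly-T beads, and libraries were made by a standard Illumina protocol. The submitters' processing notes name CASAVA, Trimmomatic 0.36, HISAT2 2.0.5 and featureCounts 1.5.0-p3 and the mouse build GRCm38 (mm10). Their settings, such as strand and the treatment of reads with several matches, are not given in the sources used here.

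The authors deposited a table of RPKM values, in which the reads of a gene are divided by its exonic length in kilobases and by the reads assigned to genes in that library over 1000000, per the file headers and the values. The table held 33614 rows with a symbol, exon coordinates and a gene length, and 1028 of them were 0 in every library. In 26 rows the symbol had been turned into a date by a spreadsheet program, and 4 rows shared their name with another row; none of these is named in the text. RPKM multiplied by gene length came out as whole numbers of reads, within a tolerance of 0.1 reads, for over 99.9% of the genes with a value above 0 in any library, and the values of each library summed, times gene length, to 1000000. The depth recovered this way was 29243336 to 36539400 assigned reads per library. A count of 10 reads or fewer in a library, as for Il6 in each saline library, therefore limits the precision of the weakest genes. Counting error also matters for strongly changed genes that are weak in 1 group. Examples are Ubd (0 to 8 reads) and Ccl5 (12 to 18 reads) in the saline libraries, and Cd209f (11 to 17 reads) in the polyIC libraries.

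RPKM values are not counts, so the main test was limma-trend (limma 3.58.1 in R 4.3.3, empirical Bayes with an intensity trend) on log2(RPKM + 0.5), with the group as the only term and all 8 libraries. Genes with at least 1 RPKM in at least 4 libraries were tested, which left 14561. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. The 35 gene lists, 22 of pathways and tissue functions and 13 of cell type markers, were tested with limma's camera with a preset correlation of 0.01 between genes, adjusted over 34 lists, since the B cell list had only 1 tested member. Of the 556 members of all lists 435 were tested, while 119 were under the filter, and their change is not known. Camera with a correlation estimated from the residuals and limma's fry were alternatives. Of the 15 lists called, 9 up and 6 down, none was called with an estimated correlation (adjusted p from 0.234 to 0.605), where 5 lists had an unadjusted p under 0.05. Fry also called 15 lists but not 2 of those. Of the 15, 12 had the same call under all alternatives but the estimated correlation. The exceptions were the hypoxia, uterine epithelium and mitochondrially encoded lists. The list medians, means and camera directions differed in sign for the tryptophan, macrophage, endothelial and yolk sac lists, none of which was called.

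Genes were named by a rule fixed before the data were examined, as were the groups, the tests, the lists and most alternatives. It takes the 12 largest rises and the 12 largest falls among called genes with a symbol other than a predicted-gene name, a mean of at least 1 RPKM in the higher group and no overlap between the groups. It adds, for each list, the 3 called members with the smallest p, or the 2 with the highest mean where none was called, and always Ifit1, Isg15, Cxcl10, Il6 and Prl8a2. This gave 107 genes, of which 106 were tested. Of these, 27 share exonic bases with another listed gene and 6 share over 20%.

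The test was also run on simulated data for this comparison, with 200 of 14561 genes changed by known folds and library sizes, means and spreads taken from the real table. It called 41 of 67 genes changed 1.5-fold, 54 of 67 changed 2-fold and 60 of 66 changed 4-fold, all with the right sign, and 5.49% of its calls were unchanged genes. The spread of each simulated gene was drawn independently, while genes of the real libraries vary together, as the placental transcripts do. These rates therefore need not hold for the real data. Libraries of a group correlated at r = 0.935 to 0.988 across genes on the log2 scale, where genes are not independent replicates. Libraries of different groups correlated at r = 0.923 to 0.965. Saline 4 correlated more with polyIC 1 (0.965) than with the other saline libraries (0.957 to 0.964). The first principal component held 44.7% of the variance and correlated at an absolute r of 0.893 with the mean level of the trophoblast list. No 2 libraries of a group agreed within counting noise (lowest chi-square per degree of freedom 11.3), so all 8 were kept as separate libraries.

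The alternatives fixed in advance were a pseudocount of 0.1 or 1, no filter or a filter of 5 RPKM, a rescaling to TPM, scaling by median ratios, quantile normalization, limma array weights, the replicate number as a block, and leaving out each of the 8 libraries in turn. The edgeR quasi-likelihood test, foreseen for a table of raw counts, was not run. After the data were seen, 3 alternatives were added, namely the mean level of the trophoblast list as a covariate, a fit without saline 4, polyIC 1 and polyIC 2, and limma's voom on the recovered reads. Reads on the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were summed per library, with exact 95% binomial (Clopper-Pearson) intervals that cover counting error only. Figures were drawn with matplotlib 3.10.9.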

Results

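Messenger RNA was measured in mouse decidua, the maternal uterine tissue that surrounds the placenta, at E13.5 of pregnancy. The dams were wild type and had been injected with saline or with polyIC 24 hours earlier. PolyIC is a synthetic double-stranded RNA that mimics viral RNA and is used to model maternal immune activation. Each group held 4 libraries, numbered 1 to 4 in the labels. The values were RPKM (reads per kilobase of gene per 1000000 assigned reads) for 33614 genes, and 14561 of them reached 1 RPKM in at least 4 libraries and were tested. The reads assigned to genes numbered 29243336 to 36539400 in the saline libraries and 31671120 to 36082934 in the polyIC libraries. The labels do not say whether each library came from a separate dam, so the p-values measure the spread between these libraries, which may be technical. RPKM values below are means ± SD over the 4 libraries of a group. Log2 changes and folds are on the scale of log2(RPKM + 0.5), which understates the change of weakly expressed genes.

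The comparison of polyIC with saline asks which decidual transcripts differ 24 hours after the injection. Chemokine and interferon-stimulated transcripts were among the genes that rose most. On the scale of log2(RPKM + 0.5), F13a1, Fam13a and Mrc1 had the largest falls among the named genes. Cxcl9, a chemokine that attracts T cells, rose from 1.53 ± 0.21 to 163 ± 46 RPKM (log2 change 6.29, SE 0.20, adjusted p = 9.25e-06). Apod, which encodes the lipid carrier apolipoprotein D, rose from 1.16 ± 0.29 to 52.0 ± 14.7 RPKM. Ccl5, a chemokine for T cells and monocytes, rose from 0.547 ± 0.104 to 29.5 ± 7.1 RPKM, and Ccl11, which attracts eosinophils, rose from 1.68 ± 0.47 to 48.0 ± 14.0 RPKM. Saa3, an acute phase protein gene, rose from 4.44 ± 2.57 to 123 ± 40 RPKM. The other genes among the 12 largest rises were Ifit3b (log2 change 4.01), Ifit3 (3.82), Gbp10 (3.81), Ubd, a ubiquitin-like modifier gene (3.70), Irf7 (3.60), Phf11b (3.46) and Tgtp1 (3.30), with adjusted p from 2.85e-05 to 2.64e-04. Ubd had 0 to 8 reads in the saline libraries, and its log2 change lay between 2.91 and 6.93 in 20 alternatives. In all, limma-trend called 1375 of 14561 genes at a Benjamini-Hochberg adjusted p under 0.05, of which 807 rose and 568 fell. Of these, 288 rose and 73 fell at least 2-fold. At an unadjusted p under 0.05 the number was 3454. The 4 libraries of one group lay beyond all 4 of the other for 17.4% of the tested genes, against 2.86% given by chance.

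The count of changed genes moved by over 1.5 times with some libraries. It was 863 without saline 1, 779 without saline 2 and 717 without saline 3, and 2465 without saline 4, polyIC 1 and polyIC 2, the 3 libraries rich in placental transcripts described at the end. That last set was left out together after the data were seen. Of the 1375 genes, 1132 passed the test with the same sign in those 5 libraries.

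In coordinates of the GRCm38 build, Cxcl9 lies on the minus strand of chromosome 5 from 92321347 to 92328079, and Cxcl10 lies near it from 92346638 to 92348889. Ccl5 and Ccl11 lie on chromosome 11, from 83525778 to 83530518 on the minus strand and from 82057823 to 82062955 on the plus strand. Ifit3, Ifit3b and Ifit1 are neighbours on the plus strand of chromosome 19, from 34583531 to 34588731, from 34607970 to 34613401 and from 34640871 to 34650009. Irf7 lies on the minus strand of chromosome 7 from 141262706 to 141266481. Of the genes that fell, F13a1 lies on the minus strand of chromosome 13 from 36867178 to 37050244, and Mrc1 lies on the plus strand of chromosome 2 from 14229392 to 14332057. The values count reads over the annotated exons of each gene. Ifit3 and Ifit3b, Tgtp1 and its neighbouring copy, the class I genes of the H2-Q cluster, and the granzyme and prolactin gene families have near-identical copies, so the split of reads between copies is uncertain. Gbp10, Gbp6, Cfb, Foxp3 and Apoa4 share over 20% of their exonic bases with another listed gene, and whether the counting used strand is not given in the sources used here. For Gbp10, Gbp6 and Cfb the other gene lies on the same strand, so strand could not separate their reads.

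Type I interferon-stimulated genes rose as a block. All 41 members of this list were tested and all 41 rose, also when adjusted over the list alone, with a median log2 change of 2.08 and a range of 0.92 to 4.01. Irf7, a transcription factor that drives interferon production, rose from 15.8 ± 3.3 to 197 ± 34 RPKM. Bst2, a membrane tether of budding viruses, rose from 61.7 ± 2.0 to 307 ± 46 RPKM, and Zbp1, a nucleic acid sensor that can trigger cell death, rose from 5.38 ± 0.80 to 52.9 ± 10.3 RPKM. Ifit1, which binds viral RNA, rose from 7.95 ± 3.13 to 59.8 ± 11.6 RPKM, and Isg15, a ubiquitin-like modifier, rose from 50.8 ± 12.7 to 397 ± 93 RPKM. The list stood above other genes in limma's camera test with its preset correlation (adjusted p = 3.82e-53). With an estimated correlation the list was not called (adjusted p = 0.234 with an estimated correlation).

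Interferon-gamma-inducible genes rose in 18 of 20 tested members, also 18 when adjusted over the list alone, with a median log2 change of 2.31. The name of the list does not show that interferon gamma raised these genes, which was not tested. Besides Cxcl9, the guanylate-binding GTPase genes Gbp2 (26.9 ± 1.7 to 250 ± 69 RPKM) and Gbp6 (4.11 ± 0.67 to 36.8 ± 9.3 RPKM) rose. Class I antigen presentation genes rose in 19 of 19 tested members, also 19 when adjusted over the list alone, with a median log2 change of 1.27. The class I gene H2-Q6 rose from 45.0 ± 2.6 to 327 ± 52 RPKM, H2-Q4 rose from 21.1 ± 2.3 to 91.1 ± 14.2 RPKM, and Tap1, which carries peptides to class I molecules, rose from 6.0 ± 0.27 to 21.1 ± 2.6 RPKM. Camera gave an adjusted p of 3.84e-27 for the interferon-gamma list and of 1.70e-28 for the class I list. Neither list was called with an estimated correlation (adjusted p = 0.234 for each with an estimated correlation).

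**Figure D1:**
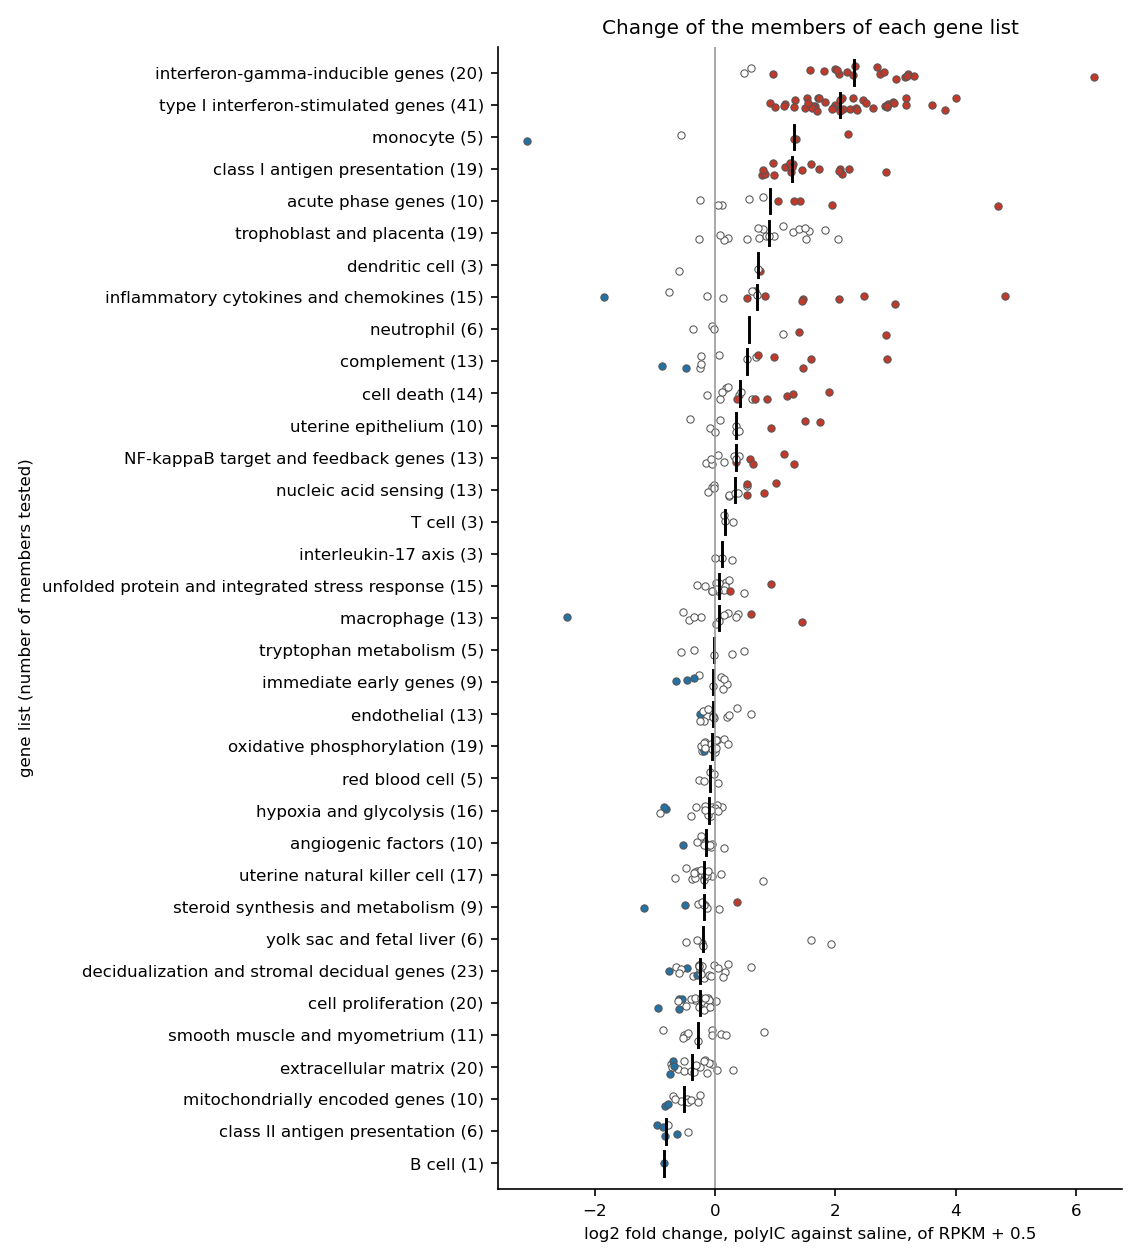
Log2 fold change (x axis, polyIC against saline, of RPKM + 0.5) of each tested member of the 35 gene lists (y axis, number of tested members in parentheses). Filled points passed adjusted p under 0.05 in limma (red for a rise, blue for a fall), open points did not, black bars are list medians, and vertical scatter within a list is arbitrary; all 41 type I interferon-stimulated genes lie above 0.

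Class II antigen presentation genes went the other way. Of 6 tested members 4 fell and none rose, and 6 fell when adjusted over the list alone, with a median log2 change of -0.81. H2-Ab1 fell from 110 ± 13 to 62.7 ± 18.8 RPKM (adjusted p = 0.0389), H2-Eb1 fell from 39.8 ± 2.0 to 20.9 ± 7.0 RPKM, and H2-DMa, which helps load peptides on class II molecules, fell from 1.45 ± 0.25 to 0.755 ± 0.139 RPKM. Camera gave an adjusted p of 1.92e-04 (adjusted p = 0.267 with an estimated correlation). H2-Ab1 lost its call in 9 of 20 alternatives, H2-Eb1 in 4 of 20 and H2-DMa in 2 of 19, and all 3 lost it without saline 1 and without saline 2. H2-Ab1 and H2-Eb1 were lower in the polyIC libraries rich in placental transcripts, at 47.4 and 15.3 RPKM in polyIC 1 and 47.1 and 15.1 RPKM in polyIC 2, than in polyIC 3 (71.0 and 23.4 RPKM) and polyIC 4 (85.3 and 29.7 RPKM). Without saline 4, polyIC 1 and polyIC 2 the median of the class II antigen presentation list was -0.52, and the list kept its call.

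Inflammatory cytokine and chemokine genes rose in 9 of 15 tested members and fell in 1, with 11 and 2 when adjusted over the list alone. Ccl2, a monocyte attractant, rose from 1.67 ± 0.31 to 17.7 ± 7.2 RPKM, and Ccl8 rose from 5.98 ± 0.95 to 17.1 ± 3.1 RPKM. Cxcl10, an interferon-induced chemokine, rose from 0.484 ± 0.127 to 9.86 ± 6.19 RPKM (adjusted p = 0.00223). The member that fell was Il1a, which encodes interleukin 1 alpha, from 13.4 ± 5.8 to 3.11 ± 0.80 RPKM (adjusted p = 0.0146, and 0.0993 at most in 20 alternatives, of which 2 ended its call, without saline 2 and without the 3 libraries rich in placental transcripts). Il6 stayed under the filter with 4 to 10 reads in the saline and 14 to 54 reads in the polyIC libraries, or 0.0986 ± 0.0362 and 0.342 ± 0.213 RPKM. With no filter its adjusted p was 0.212. Camera gave an adjusted p of 1.31e-06 for the list (adjusted p = 0.267 with an estimated correlation).

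Further innate immune lists rose in part. Acute phase genes rose in 5 of 10 tested members (7 adjusted over the list alone), among them Saa3, Hp, which encodes the haemoglobin-binding haptoglobin (5.01 ± 2.17 to 20.1 ± 4.9 RPKM), and Cp, which encodes the copper carrier ceruloplasmin (4.20 ± 0.77 to 12.3 ± 4.0 RPKM). Cell death genes rose in 6 of 14 members (9 adjusted over the list alone), led by Mlkl, the effector of necroptosis, from 12.7 ± 2.0 to 48.7 ± 8.6 RPKM, with Tnfsf10 (1.20 ± 0.15 to 3.74 ± 1.10 RPKM) and Casp4 (4.62 ± 0.63 to 11.4 ± 2.7 RPKM). NF-kappaB target and feedback genes rose in 5 of 13 members (9 adjusted over the list alone), with Nfkbie, Vcam1 and Relb at log2 changes of 1.14, 1.31 and 0.58. Nucleic acid sensing genes rose in 4 of 13 members (9 adjusted over the list alone), with Tlr3, the endosomal receptor of double-stranded RNA, at 1.48 ± 0.21 and 3.53 ± 0.79 RPKM, Trim25 at a log2 change of 0.80 and Myd88 at 0.53. Camera gave adjusted p of 1.12e-04, 2.14e-06, 2.92e-04 and 2.92e-04 for these 4 lists in this order (adjusted p = 0.267 for each with an estimated correlation). Complement genes rose in 5 and fell in 2 of 13 members (7 and 2 adjusted over the list alone). Cfb, of the alternative pathway, rose from 25.2 ± 2.3 to 189 ± 45 RPKM, C4b rose from 9.30 ± 1.96 to 29.2 ± 6.7 RPKM and C1ra rose from 18.9 ± 4.1 to 53.6 ± 15.5 RPKM, and the list as a whole did not pass (camera adjusted p = 0.0525), though it was called in 13 of 22 alternatives, with adjusted p from 0.0200 to 0.636. The interleukin-17 axis had no called member among 3 tested (1 adjusted over the list alone), with Il23a at 7.90 ± 0.97 and 8.24 ± 3.08 RPKM and Il17ra, called in 2 of 19 alternatives, at 2.33 ± 0.21 and 2.94 ± 0.29 RPKM in saline and polyIC (camera adjusted p = 0.292). This list has 11 members, and the rest were under the filter and not tested. Cp, C1ra and Relb each lost their call in 1 alternative, the replicate block.

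**Figure D2:**
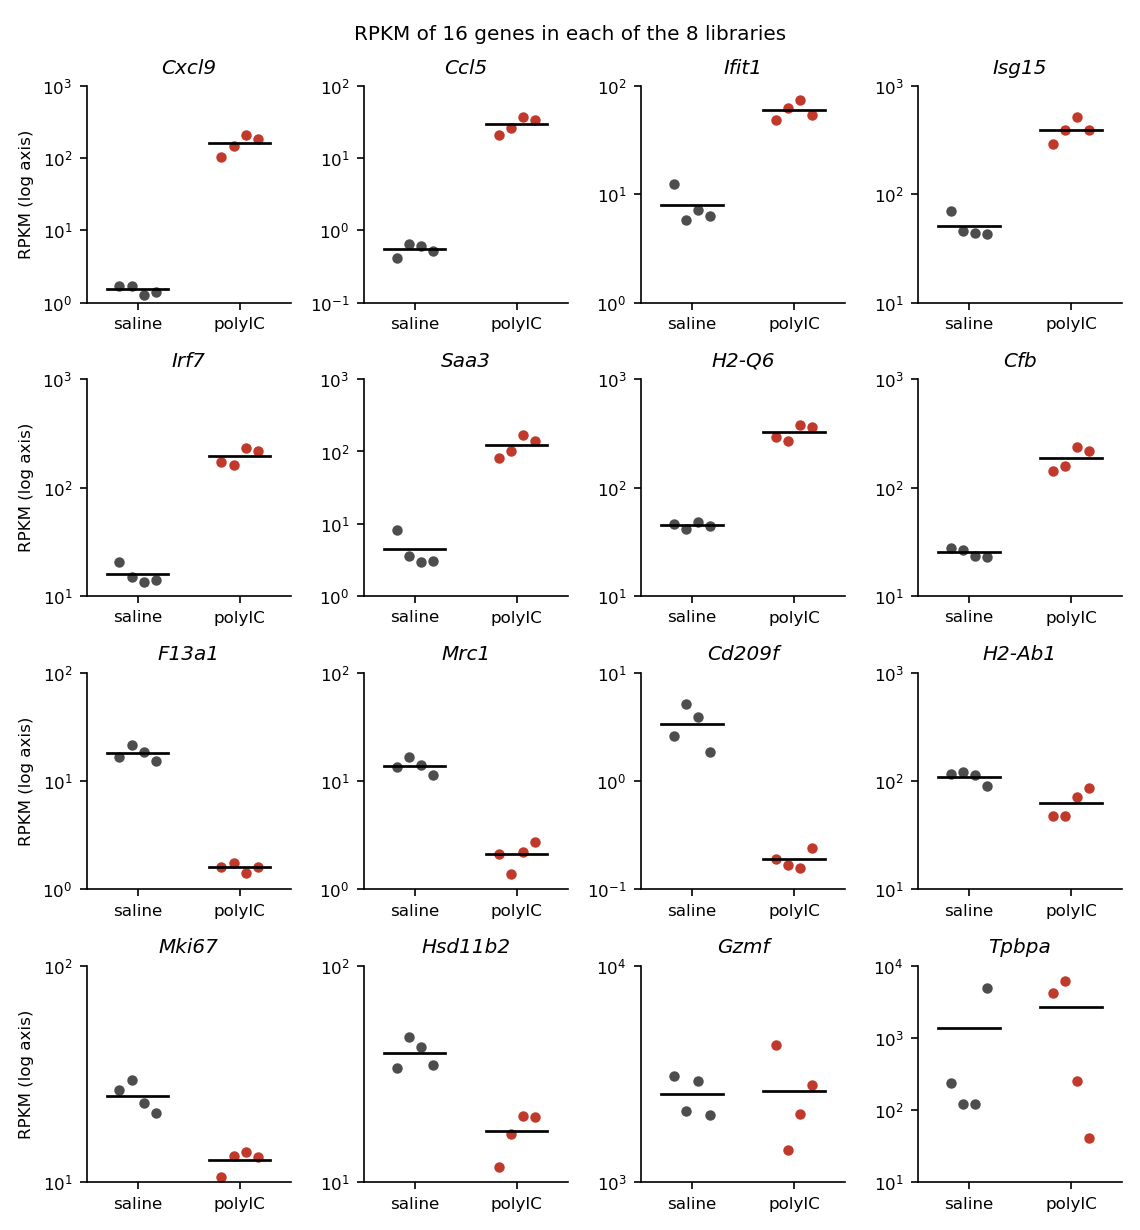
RPKM of 16 genes (y axes, log scale) in the 4 saline libraries (grey) and the 4 polyIC libraries (red), each point a library in the order 1 to 4 and each black line the group mean. Cxcl9 averaged 1.53 RPKM in saline and 163 RPKM in polyIC, F13a1 averaged 18 and 1.60 RPKM, and the placental gene Tpbpa was split within both groups.

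Of the 12 largest falls, 6 came from genes known from macrophages, a grouping made after the values were seen and not tested as a set. F13a1, the A subunit of coagulation factor XIII, fell from 18 ± 2.7 to 1.60 ± 0.14 RPKM (log2 change -3.13, SE 0.11, adjusted p = 9.25e-06). Mrc1, the mannose receptor CD206, fell from 13.8 ± 2.1 to 2.12 ± 0.57 RPKM, and the lectin genes Cd209f (3.33 ± 1.43 to 0.189 ± 0.038 RPKM) and Clec10a (2.98 ± 0.47 to 0.373 ± 0.102 RPKM) fell. Fcrls, an Fc receptor-like scavenger receptor, fell from 7.59 ± 0.94 to 1.26 ± 0.37 RPKM, and Retnla, a gene of alternatively activated macrophages, fell from 5.38 ± 1.72 to 1.03 ± 0.41 RPKM. The other falls among the 12 largest were Fam13a (log2 change -2.70), Ngfr, a neurotrophin receptor (-2.23), Mir5116 (-2.05), Mir7041 (-1.90), Il1a (-1.85) and Col11a1, a fibrillar collagen (-1.84). Mir5116, which lost its call in 10 of 19 alternatives, rested on 10 or fewer reads in each library and lies within an exon of Mmgt1, Mir7041 rested on 3 or fewer reads and lies within the span of Lrig1, and such short genes say little about the microRNAs in poly(A)-selected libraries.

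No immune cell list passed camera in the main fit, while fry called the neutrophil list (adjusted p = 0.00303). The macrophage list had 2 members that rose and 1 that fell among 13 tested, with the same numbers adjusted over the list alone. Fcgr1, a high-affinity antibody receptor, rose from 2.03 ± 0.30 to 6.42 ± 1.12 RPKM, Itgam rose from 9.28 ± 0.92 to 14.5 ± 2.8 RPKM, and Mrc1 fell. The list median was 0.06, the mean -0.06 and the camera adjusted p 0.723. The monocyte list had 3 members that rose and 1 that fell among 5 (3 and 2 adjusted over the list alone), with Plac8 (42.2 ± 4.7 to 108 ± 10 RPKM) and Ms4a4c (0.521 ± 0.179 to 4.24 ± 1.01 RPKM) up, F13a1 down and a camera adjusted p of 0.210. Of 6 neutrophil genes 2 rose, also 2 adjusted over the list alone. These were S100a9, an alarmin abundant in neutrophils (4.43 ± 0.78 to 36.3 ± 13 RPKM), and Csf3r, the receptor of granulocyte colony-stimulating factor (0.465 ± 0.065 to 2.03 ± 0.32 RPKM), and the list did not pass (camera adjusted p = 0.0525), though it was called in 11 of 22 alternatives, with adjusted p from 0.00223 to 0.631. Uterine natural killer cell genes had no call among 17 tested members, nor adjusted over the list alone, with Gzmf at 2566 ± 544 and 2648 ± 1245 RPKM and Gzmg at 1150 ± 235 and 1117 ± 512 RPKM in saline and polyIC (camera adjusted p = 0.144). T cell genes had none among 3, also none adjusted over the list alone, with Trbc1 at 4.94 ± 1.13 and 5.93 ± 2.53 RPKM and Foxp3 at 1.58 ± 0.09 and 1.81 ± 0.23 RPKM (camera adjusted p = 0.292). The T cell list has 14 members, and the rest were under the filter and not tested. The dendritic cell list had 1 call among 3, the integrin gene Itgax (1.22 ± 0.28 to 2.38 ± 0.55 RPKM), with 2 up and 1 down adjusted over the list alone and a camera adjusted p of 0.467. The B cell list had 1 tested member, the antibody chain gene Ighm, which fell from 4.65 ± 0.89 to 2.38 ± 0.61 RPKM. Itgam lost its call in 10 of 20 alternatives, Itgax in 9 of 19 and Ighm in 3 of 19.

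Some stromal and matrix genes fell, while most of them did not pass the test. Decidualization and stromal decidual genes fell in 3 of 23 tested members (4 adjusted over the list alone), with a median log2 change of -0.24. Pgr, the progesterone receptor, fell from 9.47 ± 0.98 to 6.75 ± 0.76 RPKM, Bmp8a fell from 9.23 ± 0.89 to 5.33 ± 1.44 RPKM, and the transcription factor gene Fosl2 fell from 16.2 ± 1.0 to 13.1 ± 1.1 RPKM. Prl8a2, which encodes decidual prolactin-related protein, was at 675 ± 95 and 472 ± 261 RPKM in saline and polyIC (adjusted p = 0.258). It stood at 857 RPKM in polyIC 2, at 297 to 409 RPKM in the other polyIC libraries and at 604 to 812 RPKM in saline, and it was called in 3 of 20 alternatives, with array weights, without polyIC 2 and without the 3 libraries rich in placental transcripts, with adjusted p down to 0.00771. Extracellular matrix genes fell in 3 of 20 members (6 adjusted over the list alone), with a median log2 change of -0.38, namely the proteoglycan gene Lum (82.2 ± 11 to 51.3 ± 9.9 RPKM), the laminin gene Lama4 (34.9 ± 6.0 to 21.3 ± 3.4 RPKM) and the elastin gene Eln (41.8 ± 6.9 to 25.0 ± 6.0 RPKM). Lama4 and Eln were lowest within each group in those 3 libraries, at 26.1 and 31.5 RPKM in saline 4, 19.6 and 20.4 RPKM in polyIC 1 and 17.3 and 19.4 RPKM in polyIC 2, and without them the median of the extracellular matrix list was -0.26. The smooth muscle gene Myh11 had the same order, at 1603 RPKM in saline 4 against 1980 to 2440 RPKM in the other saline libraries, and at 973 and 1182 RPKM in polyIC 1 and 2 against 2008 and 1841 RPKM in polyIC 3 and 4, so the share of muscle in the samples was not separated from these falls. Camera gave adjusted p of 0.00571 and 1.92e-04 for the decidualization and matrix lists (adjusted p = 0.267 for each with an estimated correlation). All 6 genes said to have fallen here lost their calls in 4 to 9 of 20 alternatives.

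Steroid genes had 2 falls and 1 rise among 9 tested members, also when adjusted over the list alone. Hsd11b2, which inactivates glucocorticoids, fell from 39.4 ± 6.1 to 17.2 ± 3.9 RPKM (adjusted p = 0.00526), Scarb1, a lipoprotein receptor gene, fell from 3.66 ± 0.44 to 2.43 ± 0.09 RPKM, and Ldlr rose from 7.29 ± 0.52 to 9.61 ± 1.29 RPKM (camera adjusted p = 0.120 for the list). The angiogenic factor list had 1 fall among 10, Vegfa (90.4 ± 8.0 to 62.8 ± 12.8 RPKM), the same adjusted over the list alone, and did not pass (camera adjusted p = 0.120). The endothelial list had 1 fall among 13, the receptor gene Kdr (12.6 ± 0.5 to 10.5 ± 0.5 RPKM), the same adjusted over the list alone (camera adjusted p = 0.445). Uterine epithelium genes rose in 3 of 10 members, also 3 adjusted over the list alone. Muc1, a surface mucin gene, rose from 5.95 ± 0.97 to 17.7 ± 3.5 RPKM, Sprr2f rose from 2.89 ± 1.17 to 10.7 ± 3.5 RPKM, and Tacstd2 rose from 2.24 ± 0.31 to 4.86 ± 1.45 RPKM (camera adjusted p = 0.0328 for the list, adjusted p = 0.267 with an estimated correlation), a list that lost its call in 5 of 22 alternatives. The smooth muscle and myometrium list had no call among 11 members, nor adjusted over the list alone, with Myh11 at 2036 ± 347 and 1501 ± 501 RPKM and Des, called in 1 of 20 alternatives, at 901 ± 107 and 1031 ± 169 RPKM (camera adjusted p = 0.232). Ldlr, Vegfa, Kdr and Sprr2f lost their calls in 11, 9, 6 and 1 of 20 alternatives, and Tacstd2 in 4 of 19.

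Cell proliferation genes fell in 4 of 20 tested members (5 adjusted over the list alone), with a median log2 change of -0.26. Mki67, the Ki-67 marker of cycling cells, fell from 25.2 ± 3.9 to 12.7 ± 1.4 RPKM (adjusted p = 0.00233), Aurkb, a mitotic kinase gene, fell from 1.58 ± 0.11 to 0.881 ± 0.121 RPKM, and Top2a fell from 13.8 ± 1.7 to 8.88 ± 1.07 RPKM. Camera gave an adjusted p of 5.79e-06 (adjusted p = 0.320 with an estimated correlation). Hypoxia and glycolysis genes fell in 2 of 16 members (3 adjusted over the list alone), Car9 (2.38 ± 0.47 to 1.09 ± 0.11 RPKM) and the hexokinase gene Hk2 (53.4 ± 5.2 to 31.3 ± 11.1 RPKM), with a list median of -0.09 (camera adjusted p = 0.0423, adjusted p = 0.605 with an estimated correlation). The hypoxia list lost its call in 9 of 22 alternatives, among them 6 of the 8 fits that left out 1 library, fry and the 5 RPKM filter. Mitochondrially encoded genes fell in 2 of 10 members (5 adjusted over the list alone), mt-Cytb (1785 ± 366 to 1024 ± 95 RPKM) and mt-Nd4 (1046 ± 236 to 579 ± 79 RPKM), with a median log2 change of -0.51 (camera adjusted p = 1.23e-04, adjusted p = 0.378 with an estimated correlation). Mitochondrially encoded transcripts took 1.48% to 1.57% of the reads in saline 1 to 3, 0.915% in saline 4 and 0.813% to 1.04% in the polyIC libraries. mt-Cytb and mt-Nd4 each lost their calls in 8 of 20 alternatives, and Hk2 in 9. Top2a lost its call in 1, with the replicate block.

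The remaining lists did not pass as sets. Of all lists not called, oxidative phosphorylation was called in 4 of 22 alternatives, angiogenic factors in 3, the stress response in 2, trophoblast and placenta in 2 of 21, and the steroid, natural killer cell and monocyte lists in 1 each, besides complement and neutrophil. Nuclear oxidative phosphorylation genes fell in 2 of 19 members, also 2 adjusted over the list alone, Ndufs1 and Cox4i1, which fell by 0.20 and 0.19 on the log2 scale and lost their calls in 11 and 15 of 20 alternatives (camera adjusted p = 0.120). Immediate early genes fell in 3 of 9 members, also 3 adjusted over the list alone, with Ier2, Ier3 and Egr1 at log2 changes of -0.35, -0.47 and -0.66 and lost calls in 3 of 19, 3 of 20 and 6 of 19 alternatives (camera adjusted p = 0.381). Of the unfolded protein and integrated stress response genes 2 of 15 rose, also 2 adjusted over the list alone. Ddit3, which encodes the stress transcription factor CHOP, rose from 45.3 ± 5.3 to 86.8 ± 10.6 RPKM (adjusted p = 0.00131), and Asns, which lost its call in 13 of 20 alternatives, rose from 5.92 ± 0.31 to 7.14 ± 0.40 RPKM (camera adjusted p = 0.120). Tryptophan metabolism genes had no call among 5, nor adjusted over the list alone, with Tdo2 at 24.9 ± 3.6 and 35.5 ± 8.7 RPKM and Wars at 27.1 ± 4.0 and 26.7 ± 3.3 RPKM (camera adjusted p = 0.890).

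Placental transcripts divided the libraries within both groups. Tpbpa, a marker of the spongiotrophoblast, stood at 4980 RPKM in saline 4, 4206 in polyIC 1 and 6169 in polyIC 2, and at 41.0 to 254 RPKM in the other 5 libraries. No trophoblast and placenta gene was called among 19 tested members, nor adjusted over the list alone, with Tpbpa at 1365 ± 2411 and 2667 ± 3019 RPKM and Tpbpb at 690 ± 1275 and 1479 ± 1660 RPKM in saline and polyIC (camera adjusted p = 0.303). The mean log2 level of the 19 members differed by 0.94 between the groups (exact permutation p = 0.686). Yolk sac and fetal liver genes had no call among 6 members and red blood cell genes none among 5, nor adjusted over either list alone (camera adjusted p = 0.686 and 0.723). Rbp4, called in 2 of 20 alternatives, stood at 32.6 ± 4.9 and 24.2 ± 9.7 RPKM, Apoa4 at 14.6 ± 1.7 and 13 ± 3.5 RPKM, Hbb-bs at 65.4 ± 9.5 and 57.4 ± 22.6 RPKM and Hba-a1 at 32.4 ± 9.7 and 36.1 ± 17.5 RPKM in saline and polyIC. The type I interferon-stimulated genes separated the groups, and within each group they were lowest in the libraries rich in placental transcripts. Their mean log2 level was 3.12 in saline 4 and 3.20 to 3.56 in the other saline libraries, and it was 5.16 in polyIC 1, 5.42 in polyIC 2, 5.83 in polyIC 3 and 5.44 in polyIC 4.

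**Figure D3:**
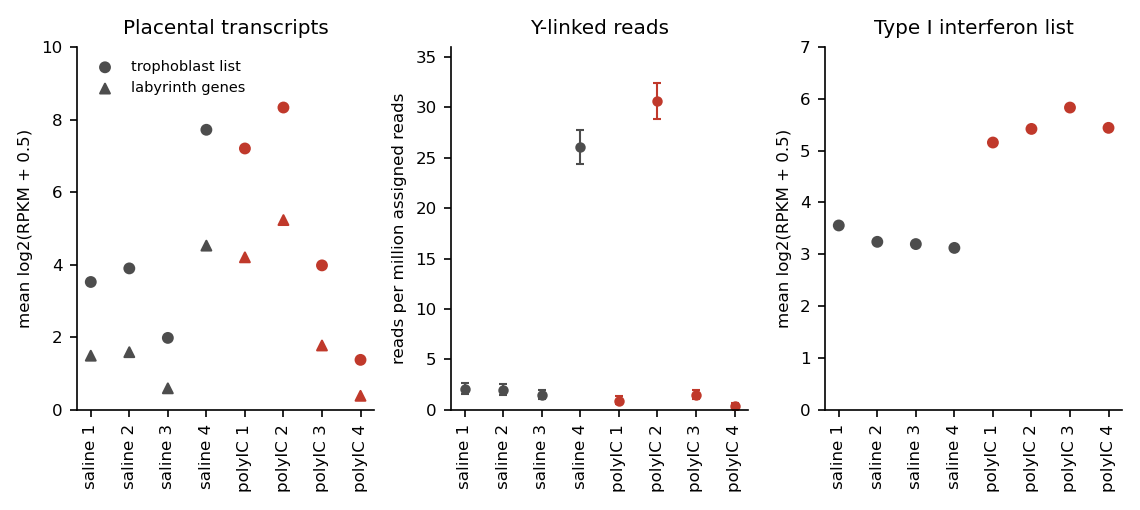
Left, mean log2(RPKM + 0.5) of the trophoblast list (circles) and of labyrinth genes (triangles) in each library; middle, reads on 4 Y-linked genes per 1000000 assigned reads with exact 95% binomial intervals that cover counting error only; right, mean log2(RPKM + 0.5) of the type I interferon list, with saline in grey and polyIC in red. Saline 4, polyIC 1 and polyIC 2 held the highest trophoblast levels, while the interferon list separated all 4 polyIC libraries (5.16 to 5.83) from all 4 saline libraries (3.12 to 3.56).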

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

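All tests of explanations in this part, on labyrinth genes, on polyIC and on a wrong label, were chosen only after the result was seen. Among 4 libraries, a value was singled out when its gap to the nearest other library took up more of the group's range than the 95% critical value of Dixon's ratio. This singled out 24 of 292 groups of 4 values, where chance gives about 14.6, and 10 of the 24 were in saline 4.

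Placental transcripts set saline 4, polyIC 1 and polyIC 2 apart. Among the saline libraries, saline 4 was singled out for Tpbpa (4980 RPKM against 123 to 234) and Tpbpb (2603 RPKM against 33.5 to 77.1). A candidate explanation is placental tissue of more than 1 layer in the dissected sample. Of 9 genes of the labyrinth, a layer that invading trophoblast cells do not form, the 4 in no fixed list had a mean log2 level 2.34 higher in the lowest of the 3 libraries than in the highest of the other 5 (2.43 for all 9), mostly through Ctsm and Ctsr, while Tfeb and Slc16a3 moved little. A wrongly labelled polyIC library is argued against for saline 4, since its type I interferon-stimulated genes lay -0.21 (log2) from the mean of the other saline libraries. An effect of polyIC on the placental transcripts stays open, because the groups overlapped with an exact permutation p of 0.686, which does not show that they were equal.

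Y-linked reads were singled out in both groups. They made up 26.1 per 1000000 assigned reads in saline 4 (952 reads, exact 95% interval 24.4 to 27.8) against 1.45 to 2.05 in saline 1 to 3, and 30.6 per 1000000 in polyIC 2 (1104 reads, interval 28.8 to 32.5) against 0.368 to 1.46 in the other polyIC libraries. PolyIC 1, the other library rich in placental transcripts, held 29 such reads, or 0.916 per 1000000.

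Saline 4 was also singled out for 36539400 assigned reads against 29243336 to 30341765, for the share of its 10 most abundant genes (9.65% against 9.94% to 9.99%), for mitochondrially encoded reads (0.915% against 1.48% to 1.57%) and for the mean log2 level of that list (7.75 against 8.37 to 8.47). It was singled out for mt-Cytb (1238 RPKM against 1938 to 2002), Eln (31.5 RPKM against 44.0 to 46.5) and Tlr3 (1.17 RPKM against 1.57 to 1.6). Saline 1 was singled out for higher Isg15 (69.8 RPKM against 43.4 to 45.9), Ifit3 (62.6 RPKM against 31.5 to 35.5), Ifit3b (14.1 RPKM against 6.79 to 7.75) and Saa3 (8.26 RPKM against 2.93 to 3.56).

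Saline 2 was singled out for Vcam1 (0.663 RPKM against 0.509 to 0.531), S100a9 (3.28 RPKM against 4.74 to 4.95) and the mean log2 levels of the hypoxia and glycolysis list (4.39 against 4.50 to 4.50) and the immediate early list (3.22 against 3.37 to 3.39). Saline 3 was singled out for Vegfa (102 RPKM against 85.0 to 87.5) and Aurkb (1.42 RPKM against 1.62 to 1.65). PolyIC 1 was singled out for Vegfa (81.9 RPKM against 55.0 to 58.4) and mt-Nd4 (696 RPKM against 525 to 554), and polyIC 2 for Itgam (10.4 RPKM against 15.5 to 16.3).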

How the results depend on the processing

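The fits with a trophoblast covariate, without 3 libraries together and with voom were chosen only after the result was seen. No called gene or list changed sign under any alternative. Of 89 called named genes, 57 kept their call in all alternatives run on them. The 1375 changed genes became 2715 with array weights (1483 up, 1232 down) and 2465 without saline 4, polyIC 1 and polyIC 2 (1421 up, 1044 down); array weights were 0.322 to 0.483 for those 3 libraries and 1.36 to 2.33 for the others. With a 5 RPKM filter, which tested 7460 genes, 335 fell and 233 changed at least 2-fold. Leaving out 1 library gave 717 to 1296 changed, 504 to 812 raised, 213 to 514 lowered, 324 to 385 changed at least 2-fold and 14 to 18 called lists. With the replicate block 543 genes were called (393 up, 150 down), and the labels do not say whether equal numbers pair libraries. Deviations of equal numbers correlated at -0.70 to 0.32 and 0 libraries correlated best with their own number. That check cannot exclude a pairing, since the placental transcripts of saline 4, polyIC 1 and polyIC 2 also enter these deviations. With an estimated correlation 0 lists were called. Other alternatives moved these counts by less than 1.5 times, such as 1868 with the trophoblast covariate, which kept 1355 of the 1375, and 1435 with voom on recovered reads, which kept 1312. Rescaling to TPM gave 973. The median change over all genes stayed within -0.03 and 0.01 under each scaling, and quantile normalization put the share of rises at 49.0% against 58.7%. The cause of these shifts was not tested otherwise. In 1 of 35 splits of the 8 libraries, the real one, as many genes changed or changed at least 2-fold. The same held for the larger and the smaller of the 2 directions, and this rank argues against chance for these counts. The highest of the others was 1 changed gene. All other splits put polyIC libraries on both sides, which adds to the spread within a side, so their low counts carry no further weight. For lists 8 of 35 splits called 15 or more, with 15 as the highest of the others, but this count cannot decide about chance. Each of those others exchanged only 1 saline with 1 polyIC library and so kept part of the real contrast. Splits with 2 saline and 2 polyIC libraries on each side called 0 to 8 lists. Each side then held as many polyIC as saline libraries, so camera with the preset correlation could call lists without a contrast of the groups.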

Other observations

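The tests in this part were chosen only after the result was seen, except the test of pan-leukocyte genes. Gene families were also read from symbols, with each symbol stem of at least 8 tested members taken as a set. Of 200 stems 20 passed camera at an adjusted p under 0.05 with the preset correlation and none of those described here with an estimated correlation (adjusted p from 0.469 to 0.722). The Schlafen genes, of which the fixed lists hold 0, rose in 8 of 8 tested members with a median log2 change of 1.58, among them Slfn4 (4.25 ± 0.61 to 29.7 ± 5.1 RPKM, SD, n = 4) and Slfn2 (34.6 ± 3.8 to 118 ± 18 RPKM). Guanylate-binding protein genes rose in 10 of 10 members. Regulatory subunits of the proteasome (Psmd) rose in 4 of 14 members by small amounts, with Psmd4 at 54.2 ± 1.2 and 70.7 ± 3.9 RPKM. This count was 1 without saline 2, 2 without saline 3, without polyIC 3 or without polyIC 4, and between 1 and 8 over all alternatives. Kinesin genes (Kif) fell in 4 of 26 members, among them the mitotic motors Kif23 (3.13 ± 0.28 to 1.75 ± 0.30 RPKM) and Kif11 (4.48 ± 0.85 to 2.62 ± 0.43 RPKM, call lost in 6 of 19 alternatives). The kinesin count was 1 without saline 2 or saline 3, 2 without saline 1, saline 4, polyIC 2 or polyIC 4, and between 1 and 8 over all alternatives. Collagen genes fell in 3 and rose in 1 of 28 members, with Col15a1 down from 84.1 ± 12.9 to 41.0 ± 7.2 RPKM and Col23a1 up from 1.04 ± 0.15 to 2.25 ± 0.15 RPKM. The falls among collagen genes numbered 2 without saline 2 or saline 3, and 5 without polyIC 1 or polyIC 3. Without saline 4, polyIC 1 and polyIC 2 there were 7 falls and 2 rises, while the median went from -0.49 to -0.25. The stem medians kept their sign in all 20 alternatives.

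Ifi27, whose name marks it as interferon-inducible, fell. It went from 14.5 ± 1.1 to 7.54 ± 0.31 RPKM (SD, n = 4, log2 change -0.90, adjusted p = 1.44e-04), and its adjusted p lay between 3.89e-05 and 0.00753 in 20 alternatives. Ifi27l2a rose from 27.6 ± 8.4 to 96.8 ± 24.6 RPKM. Of 14 tested genes with a symbol of Ifi followed directly by a number and at most a short ending, 12 rose, many of them from other families. That count leaves out Ifi27l2a and the Ifit genes. Ifi27 and Ifi27l2a were chosen after their values were seen.

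The rise of the type I interferon-stimulated genes was set against the makeup of the tissue. More leukocytes in the tissue are argued against as the whole cause, since 10 pan-leukocyte genes had a median log2 change of 0.13 (SD 0.30 over genes) against 2.08 for the list, though 1 of the 10, Cd53, was called as raised (log2 change 0.52, adjusted p = 0.0349, call lost in 9 of 19 alternatives) and Cd52 was at 0.76 (adjusted p = 0.0699). Without saline 4, polyIC 1 and polyIC 2 the median of the list was 2.22, so the rise did not depend on those libraries. The list already separated all 4 polyIC libraries from all 4 saline libraries, which largely fixed this outcome. It is therefore no independent test of unequal placental tissue. A response of cells already in the decidua stays open and was not tested here.

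Mrc1, F13a1, Clec10a, Cd209f, Fcrls and Mgl2, all known from tissue macrophages, fell together with a median log2 change of -2.31. Mgl2 (4.04 ± 0.87 to 0.770 ± 0.204 RPKM) was chosen after its values were seen. Fewer macrophages in the tissue are argued against as the whole cause, since the other 12 tested members of the macrophage list had a median log2 change of 0.10 (SD 0.54 over genes). Of these 12, Fcgr1 and Itgam were called as raised, and a rise per cell in such genes could hide a loss of cells. Without the 3 libraries rich in placental transcripts the 6 genes had a median of -2.29, so their fall did not depend on those libraries. All but Mgl2 had been picked as large falls with no overlap between the groups, which largely fixed this outcome. It is therefore no independent test of dilution by placental tissue. A loss of these transcripts within macrophages and a replacement of 1 macrophage population by another stay open and were not tested here.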
